A study of Mus musculus with 40 samples.

How the data were processed

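RNA from mouse cell lines, primary cells and tissues was measured on nylon filter arrays, 1 radioactively labelled sample per filter. Per the labels' protocols, RNA was extracted with Tripure reagent and treated with DNase, cDNA was labelled with 33P, filters made by Resgen were hybridized as the maker describes, and spots were quantified with Imagene software. The deposited values are linear spot intensities for 5760 spots in 40 samples. The software version, any background correction and any scaling are not given in the sources used here. The lowest intensity of each of 37 arrays was at least 7675, which is what values without background subtraction look like, so fold changes given here are compressed.

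The 3 arrays of embryonic stem cells grown without LIF hold intensities of another kind than the other 37. Nearly all of their values have decimals, and their 99th percentile lies between 60.0 and 391 times the median, against 3.87 to 17.5 times in the other arrays. The step that made them differ is not given in the sources used here.

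Samples were grouped by title, and the preadipocyte lines by source name. The proliferating C2C12 samples carry a source name that calls the line a preadipocyte line; they were grouped by their title as myoblasts. The 2 samples of 3T3-L1 were averaged, so that the preadipocyte baseline has 4 lines as replicates. Apart from those lines, nothing in the labels says that samples of a group came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

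Arrays were quantile normalized, and log2 was taken after adding an offset of 36370, the 10th percentile of all normalized intensities. Each log2 fold change is on this scale and understates the change of dim spots. Of the 5760 spots, 3420 are paired with 1 gene symbol by the platform annotation, 98 with several and 2242 with none. Of the 3420, 3346 were matched by gene identifier to a current symbol in the GRCm38.p6 annotation, used for names only; together they name 3284 genes. A gene with several spots is represented in gene lists by its brightest spot over all samples. No gene had more than 1 called spot in any comparison. Spots without a gene are unnamed here and may include controls: 271 spots were in the top 7% of every array, and 231 of these have no gene.

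Comparisons were tested two-sided with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes). All 14 groups entered 1 fit and shared a residual spread with 25 residual degrees of freedom. SEs and p-values of the preadipocyte comparisons therefore do not rest on the spread between lines alone. For 3T3-F442A adipocytes against these lines the median spot's SD within the compared groups was 0.167 and the median SE 0.125. For stroma-vascular cells against adipocytes they were 0.125 and 0.134. P-values were adjusted by Benjamini-Hochberg over all 5760 spots, and a spot was called at an adjusted p under 0.05. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, 1 spot per gene, and adjusted over all 63 tests of lists with at least 3 measured members. Of these, 15 were called with the preset correlation and 13 with an estimated one. A list's median and mean differed in sign for these lists, none of them called: cytokines and lymphocyte in macrophages against preadipocyte lines, adipocyte and lipid, cell cycle and lymphocyte in macrophages against stroma-vascular cells, fibroblast and matrix in macrophages against macrophage lines, cell cycle and endothelial in tibialis muscle, and oxidative phosphorylation in liver. Similarity of profiles was the Pearson correlation across spots of centred log2 values, with an exact permutation test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

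The named genes follow a rule: per comparison, up to 8 called genes with the largest rise and 8 with the largest fall whose samples do not overlap between groups, and up to 4 members of each list with the smallest p. Other list members are named only where they passed adjusted over their list alone. Clone and expressed-sequence names were left out of the first part and only counted. Groups, comparisons, gene lists, the naming rule and a first set of alternatives were fixed before the data were examined. These were median scaling, no scaling, a floor in place of the offset, 4 times the offset, bright spots only, only the compared groups, another variance model, averaging of a gene's spots, a replicate block, an estimated correlation for lists, other samples as the preadipocyte baseline, Spearman correlation and uncentred spots for profiles, and leaving out each replicate. Other alternatives were added after seeing the data: removal of a local trend over the table of spots, subtraction of each array's 5th percentile, array weights, and leaving out arrays that stood apart. A block for the membrane was not run, because no membrane is named.

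Replicate numbers were taken to pair samples where, with at least 3 pairs, every pair of deviations from the group means correlated above 0.1. This held for stroma-vascular cells and adipocytes, whose 3 pairs had correlations between 0.102 and 0.386, and for no other pair of groups. The counts with a block had been seen before this pairing was checked. The labels do not say that the number marks a shared animal.

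The fit was tested on simulated data with the real spot means and residual spreads and 200 changed spots per comparison. For stroma-vascular cells against adipocytes, 50.7% of spots changed by 0.50 on the log2 scale, 95.5% of those changed by 1 and 100% of those changed by 2 were called. For the embryonic stem cell comparison these shares were 61.2%, 94.0% and 100%. Of spots changed by 0.50, the share called was lowest for C2C12 (38.8%) and liver (40.3%) and highest for macrophages against macrophage lines and adipocytes against 3T3-F442A (both 74.6%). False calls were 2.69% to 7.14% of calls, above the 5% aimed at for stroma-vascular cells against adipocytes (6.82%), 3T3-F442A adipocytes (7.14%), C2C12 (6.59%) and tibialis muscle (6.47%), in 1 simulation each. Simulated spots were independent, unlike the real ones, whose deviations within groups correlated at 0.39 with those of the adjacent spot. For embryonic stem cells 178 spots were called in the simulation and 1 in the real data. Because the adjusted cut is stricter where fewer spots pass, the simulated shares do not carry over to comparisons with few calls. The number of arrays per group, 2 to 5, limits the precision of every value.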

Results

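The 40 arrays cover 14 groups of mouse samples that bear on the identity of fat cell precursors. The cultured groups were 4 preadipocyte lines (5 samples), 3T3-F442A adipocytes differentiated with rosiglitazone for 7 days (3), C2C12 myoblasts in proliferation (3) and after 7 days of differentiation to myotubes (2), the mesenchymal line C3H-10T1/2 (3), the macrophage lines Raw 264 (3) and J774 (2), and ZIN40 embryonic stem cells with (3) and without (3) LIF, the cytokine that holds them undifferentiated. The primary groups were adipocytes (3) and adherent stroma-vascular cells (3) of inguinal white fat, peritoneal macrophages (3), tibialis muscle (2) and liver (2). Stroma-vascular cells and macrophages were taken 24 h after plating. Median spot intensity per array ran from 941 to 132228. Values below are log2 fold changes ± SE from the limma fit with Benjamini-Hochberg adjusted p-values.

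Liver and tibialis muscle, the whole organs, differed in liver and skeletal muscle genes. In liver, the apolipoprotein gene Apoc1 was higher by 2.26 ± 0.23 (adjusted p = 4.04e-08) and Rbp4, the plasma retinol carrier, by 2.24 ± 0.30. Mgst1, a glutathione transferase, was higher by 2.38 ± 0.21, the selenium transport gene Selenop by 2.12 ± 0.27 and the sterol carrier gene Scp2 by 1.86 ± 0.30. In muscle, the myosin light chain gene Myl1 and the calcium pump gene Atp2a1 were higher, with fold changes of -3.40 ± 0.23 and -3.33 ± 0.22 for liver over muscle (both adjusted p = 1.20e-12). Pygm, muscle glycogen phosphorylase, changed by -1.88 ± 0.13, the enolase gene Eno3 by -1.59 ± 0.23 and Ldb3 of the Z-disc by -1.15 ± 0.21. These values rest on 2 samples per group. Leaving out any of the 4 leaves a group with 1 sample, whose spread is taken from the other groups. In these 4 fits 13 of 19 named genes always kept their call, among them all those given above. The 2 liver samples lay far apart, though: Rbp4 was 1.31 without liver replicate 1 and 3.18 without replicate 2, and Scp2 0.89 and 2.84, while the SEs come from the spread over all groups.

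Of 6 measured liver list members, 4 rose and none fell, and 4 passed when adjusted over the list alone; these were Apoc1, Rbp4, the haem carrier Hpx (1.69 ± 0.36) and the fibrinogen gene Fgb (1.38 ± 0.30). The liver list shifted up (camera adjusted p = 4.02e-08). Of 11 skeletal muscle genes, 6 fell and 7 passed when adjusted over the list alone, and the list shifted down (camera adjusted p = 1.19e-18). Of 18 oxidative phosphorylation genes 1 fell, Atp5o at -0.88 ± 0.21. Hpx and Fgb lost their call in 3 of the 4 fits without 1 sample, and Atp5o in 2; without liver replicate 1 Hpx was 0.37 and Fgb 0.65, and without replicate 2 they were 3.00 and 2.11. Adjusted over the list alone, Cox6a1 and Ndufaf7, an assembly factor, were higher and Atp5o lower, and the list did not shift (adjusted p = 0.983). Hbb-b1, a haemoglobin gene and the only erythroid marker measured, had 1.16 ± 0.32 (adjusted p = 0.0526). In all, limma called 108 spots, 72 higher and 36 lower in liver. Without liver replicate 2 the count was 199, without tibialis replicate 1 it was 48 and without tibialis replicate 2 it was 52, and only 2 spots, both lower, were called when these groups were fitted alone. Without scaling, where all spots shifted by a median of -1.53, 5632 spots were lower and 0 higher, and the liver list's median turned to -0.55.

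**Figure D1:**
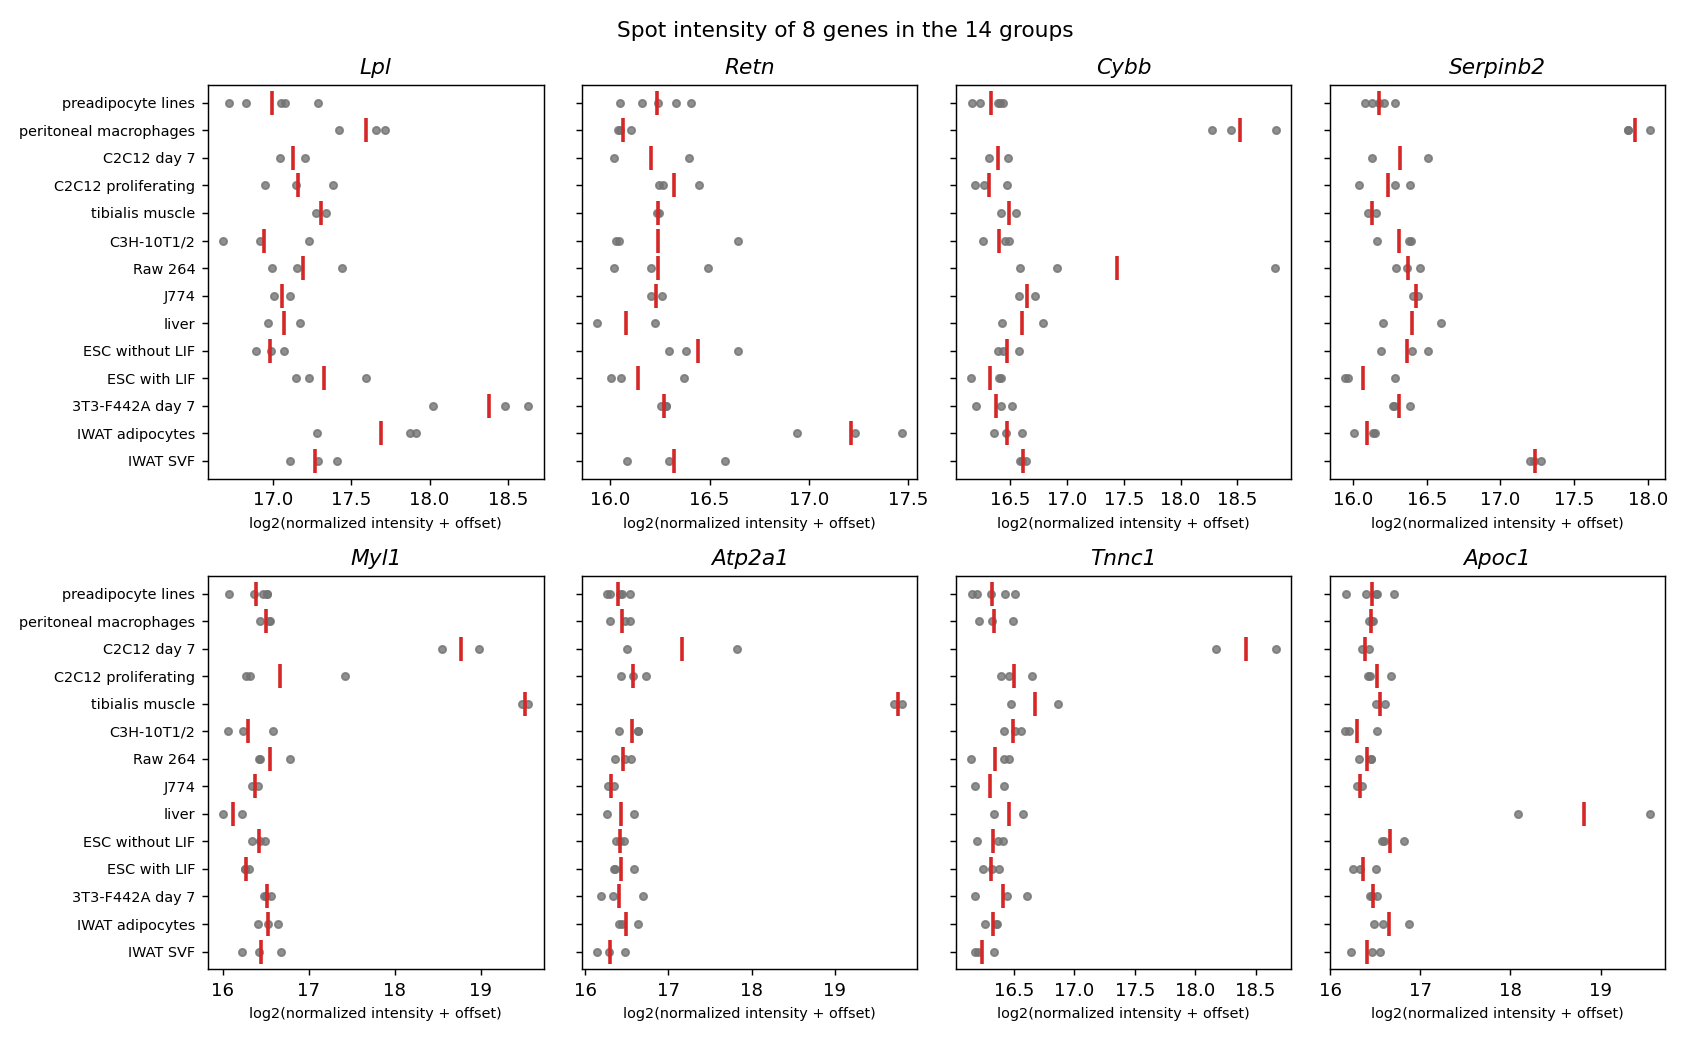
Each panel shows 1 gene's log2 normalized intensity plus offset per sample (grey points) and the mean over a group's samples (red bar) in the 14 groups. Atp2a1 is brightest in tibialis muscle, Apoc1 in liver and Retn in inguinal adipocytes, and Serpinb2 is bright in peritoneal macrophages and stroma-vascular cells.

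Myotubes were higher than proliferating C2C12 myoblasts in Myl1 and Tnnc1. Myl1 rose by 2.10 ± 0.21 (adjusted p = 5.48e-08) and Tnnc1, the troponin C of slow and cardiac muscle, by 1.92 ± 0.14 (adjusted p = 7.52e-11), with 2 and 3 samples. The secreted-protein gene C1qtnf3 rose by 0.76 ± 0.14. Among lower genes, Phtf2 had -2.17 ± 0.47, Vat1 -1.23 ± 0.28, the calcium-binding gene Sri -0.72 ± 0.15 and the Golgi SNARE gene Gosr2 -0.52 ± 0.12. Only Myl1 and Tnnc1, 2 of 7 named genes, kept their call in all 5 fits that left out a sample: Gosr2 lost it in 4, Phtf2 and Sri in 3, Vat1 in 2 and C1qtnf3 in 1.

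Of 11 skeletal muscle genes 2 rose and none fell; adjusted over the list alone, 6 were higher and 1 lower, and the list shifted up (camera adjusted p = 1.09e-08). Of 12 cell cycle genes none passed over all spots and 1, Kif20a (-0.58 ± 0.16), passed when adjusted over the list alone; the list did not shift (adjusted p = 0.131). No call over all spots was made among 4 fibroblast and matrix genes (list adjusted p = 0.0645), 18 oxidative phosphorylation genes (0.692) or 9 ribosomal protein genes (0.595). Adjusted over each list alone, Timp2 was lower, Ndufa13 higher, and Rpl15 and Rpl30 passed, 1 in each direction. Limma called 13 spots, 3 higher and 10 lower, and with median scaling 2, both higher. The leading direction turned without day 7 replicate 1 (5 higher, 0 lower), without day 7 replicate 2 (101 higher, 52 lower) and without proliferating replicate 2 (2 higher, 1 lower).

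Tibialis muscle exceeded myotubes in 41 spots and was lower in 12, but without C2C12 day 7 replicate 2 in 67 and 96. Atp2a1 was higher by 2.60 ± 0.22 (adjusted p = 9.25e-10), Pygm by 1.85 ± 0.13 (adjusted p = 5.33e-12) and the phosphofructokinase gene Pfkm by 0.80 ± 0.16, with 2 samples in each group. Tnnc1 was lower in muscle by -1.75 ± 0.16 and the imprinted fetal RNA H19 by -1.02 ± 0.26. Fdps of sterol synthesis had 2.54 ± 0.35, C9orf72 2.11 ± 0.31 and the kinase gene Alpk3 1.49 ± 0.29. Phtf2 had 2.53 ± 0.51. When each sample was left out in turn, 5 of 17 named genes kept their call in all 4 fits; H19 lost it in 3, and Pfkm, Alpk3 and Phtf2 in 2 each. Without C2C12 day 7 replicates 1 and 2 in turn, H19 was -1.61 and -0.44 and Pfkm 0.48 and 1.13. Without scaling, where all spots shifted by a median of 1.08, H19 was 0.12.

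Of 11 skeletal muscle genes, 4 were called higher and 1 lower, and 7 and 2 when adjusted over the list alone; the list shifted up (camera adjusted p = 8.76e-08). No member of the adipocyte and lipid, fibroblast and matrix, endothelial, cell cycle or oxidative phosphorylation lists was called, and none of these lists shifted (adjusted p = 0.183, 0.0627, 0.936, 0.625 and 0.189). Adjusted over the list alone, Mki67 of the cell cycle list passed, as did Atp5o and Ndufa13 of the oxidative phosphorylation list, 1 in each direction. The fibroblast and matrix list, with a median of -0.42, passed in 6 other settings, down at adjusted p = 0.0317 after removal of a local trend. Without scaling its median was 0.58, where all spots shifted by a median of 1.08. Hbb-b1 had 0.52 ± 0.32. Against 53 spots called in all, 9 were called without scaling, all higher. The count was 34 without tibialis replicate 1, 20 without tibialis replicate 2, 11 without C2C12 day 7 replicate 1 and 163 without its replicate 2.

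Stroma-vascular cells differed from the adipocytes of the same fat depot in 36 spots, 26 higher and 10 lower. Stroma-vascular cells were taken 24 h after plating and no plating is given for the adipocytes, so culture and cell type cannot be told apart. Tmsb10, an actin-monomer binding gene, was higher by 2.66 ± 0.50 (adjusted p = 0.00362) and Serpinb2, an inhibitor of plasminogen activators, by 1.14 ± 0.11 (adjusted p = 1.38e-07). Apol9a was higher by 1.08 ± 0.18, Kcnh2 by 1.06 ± 0.18 and Csf1, the macrophage growth factor, by 0.66 ± 0.13. In adipocytes the adipokine resistin, Retn, was higher (-0.89 ± 0.15, adjusted p = 0.00119), as were the triglyceride lipase gene Pnpla2 (-0.63 ± 0.11), the mRNA-decay gene Zfp36 (-0.79 ± 0.15) and Irf2bp2 (-1.36 ± 0.22). Each group has 3 samples. Of 16 named genes 6 kept their call in all 6 fits without 1 sample; Csf1 lost it in 4, Zfp36 in 2 and Pnpla2 in 1.

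All 8 measured adipocyte and lipid genes had negative values, 2 of them called, and 4 fell when adjusted over the list alone: Retn, Pnpla2, Cidec (-0.59 ± 0.19) and Lpl (-0.42 ± 0.17). This list shifted down (camera adjusted p = 1.35e-07). In a fit of these groups alone, with the replicate number as a block, adjusted p = 0.263 with an estimated correlation. No list of this comparison passed that test, which has few residual degrees of freedom in so small a fit and can hardly pass any list. All 9 ribosomal protein genes had positive values without a call over all spots, Rpl15 with 1.06 ± 0.27 and Rps3 with 1.03 ± 0.34, both passing when adjusted over the list alone; the list shifted up (adjusted p = 4.55e-06). Of 3 cytokine genes Csf1 rose and 2 passed adjusted over the list alone, with a list shift at adjusted p = 0.00794. Of 6 antigen presentation genes the immunoproteasome gene Psmb8 rose (0.52 ± 0.13; not called in 5 of the 6 fits without 1 sample) and 2 passed adjusted over the list alone; the list shift had adjusted p = 0.0285. That shift was lost when only these groups were fitted (0.0708) and with a floor (0.0507). It was also lost after removal of a local trend (0.0515) and after background subtraction (0.119). Without scaling, where all spots shifted by a median of -0.27, the list's median was -0.07. None of 4 fibroblast and matrix genes was called, 2 passed adjusted over the list alone, and the list shifted up at adjusted p = 0.00638. In the fit of all groups with an estimated correlation, this list had adjusted p = 0.0632. There the cytokine and antigen presentation lists each had 0.0498, the ribosomal protein list 0.0252 and the adipocyte and lipid list 0.000446.

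Of the 5 macrophage genes measured (Cybb, Fcer1g, Itgb2, Mpeg1, Vav1) none was called in stroma-vascular cells against adipocytes, and the list did not shift (adjusted p = 0.759). Itgb2 had 0.16 ± 0.18 and Cybb 0.14 ± 0.28. Zfp36 fell as 1 of 10 immediate early and heat shock genes, also when adjusted over the list alone (list adjusted p = 0.264). Endothelial (adjusted p = 0.234, with Cdh5 higher adjusted over the list alone), lymphocyte (0.256), cell cycle (0.369) and oxidative phosphorylation lists (0.912) did not shift; the erythroid gene Hbb-b1 had 0.26 ± 0.26. A fit of these groups alone called 112 spots, 29 of the 36 among them, and such a fit with the replicate number as a block called 231, with all 36 among them. The list shifts kept their calls under the block only with the preset correlation (ribosomal protein adjusted p = 1.73e-09). With an estimated correlation, where few residual degrees of freedom remain and hardly any list can pass, adjusted p = 0.263. Without stroma-vascular replicate 2 the unblocked count was 17 spots, without adipocyte replicate 2 it was 14 and without adipocyte replicate 3 it was 16. Without adipocyte replicate 1, 18 spots were higher and 19 lower.

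Differentiated 3T3-F442A adipocytes exceeded the preadipocyte lines in 9 spots, and none was lower. Lpl, lipoprotein lipase, was higher by 1.40 ± 0.16 (adjusted p = 4.13e-06) and the lipid droplet gene Plin5 by 1.03 ± 0.17. The glycolytic gene Aldoa was higher by 1.47 ± 0.28, the metallothionein gene Mt1 by 1.24 ± 0.27, the basement membrane collagen gene Col4a1 by 0.90 ± 0.15 and Cp, ceruloplasmin, by 0.70 ± 0.14. There were 3 samples and 4 lines. Lpl, Plin5 and Col4a1 kept their call in all 8 fits that left out a sample, while Mt1 lost it in 4 and Aldoa and Cp in 2 each. The day 7 cells were differentiated with rosiglitazone, and the baseline also holds lines other than 3T3-F442A. These fits do not separate differentiation from the drug or from differences between lines.

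Of 8 adipocyte and lipid genes, Lpl rose over all spots, 3 rose when adjusted over the list alone (Hadh, Lpl and Pnpla2), and the list shifted up (camera adjusted p = 6.13e-05). Fibroblast and matrix (adjusted p = 0.0589), cell cycle (0.328), oxidative phosphorylation (0.630), ribosomal protein (0.369) and macrophage (0.824) lists had no called member and no shift. Adjusted over the list alone, 2 ribosomal protein genes were higher and 1 lower (Rpl15, Rpl22 and Rpl27a). Removing a local trend gave 14 higher and 7 lower spots, and the single 3T3-F442A preadipocyte sample as baseline gave 10 higher and 25 lower. That baseline has no spread of its own and takes it from the other groups, so its counts rest on 1 sample. Without day 7 replicate 1 the count was 22 and without preadipocyte sample 2, a 3T3-L1 sample, it was 32 (22 higher, 10 lower). Median scaling and background subtraction each gave 2 calls, and the values without scaling 0.

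Adipocytes from fat and those made from 3T3-F442A cells differed in 142 spots, 72 higher and 70 lower in tissue adipocytes, with 3 samples each. The 3T3-F442A cells were differentiated with rosiglitazone, which this comparison does not separate from differences between tissue and culture. Zfp36 was higher by 1.08 ± 0.15 (adjusted p = 1.84e-04), Retn by 0.94 ± 0.15, elastin, Eln, by 0.94 ± 0.23 and the vesicle fusion gene Vamp2 by 1.00 ± 0.18. Lower were Rpl27a (-2.12 ± 0.34), the coatomer gene Copz2 (-2.08 ± 0.32), Aldoa (-1.89 ± 0.30), the metalloproteinase inhibitor gene Timp2 (-1.87 ± 0.32), Lgals1 (-1.58 ± 0.39), Mt1 (-1.29 ± 0.29) and Lpl (-0.69 ± 0.17). Calls held in all 6 fits without 1 sample for 8 of 18 named genes; Eln and Mt1 lost theirs in 4, and Lgals1 and Lpl in 3.

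Of 8 adipocyte and lipid genes Retn rose and Lpl fell, 3 passed when adjusted over the list alone, and the list did not shift (adjusted p = 0.328). Of 4 fibroblast and matrix genes Timp2 fell, 3 fell adjusted over the list alone and the list shifted down (adjusted p = 0.00450; adjusted p = 0.0540 with an estimated correlation). The B cell receptor gene Cd79b rose by 0.79 ± 0.21 (not called in 5 of the 6 fits without 1 sample) as 1 of 6 lymphocyte genes (list adjusted p = 0.692), and Hbb-b1 had 0.55 ± 0.26. Adjusted over the list alone, Bub1b of the cell cycle list was lower. Macrophage (adjusted p = 0.345), endothelial (0.759), cell cycle (0.955) and oxidative phosphorylation (0.0762) lists did not shift. Median scaling gave 14 higher and 49 lower spots in place of this split. Counts without adipocyte replicates 1, 2 and 3 were 34, 74 and 72, and without 3T3-F442A replicates 1, 2 and 3 they were 275 (109 higher, 166 lower), 36 and 64.

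Peritoneal macrophages exceeded stroma-vascular cells in macrophage genes. Cybb, the NADPH oxidase subunit, was higher by 1.91 ± 0.28 (adjusted p = 1.53e-04), the chemokine gene Ccl9 by 1.85 ± 0.29, the protease inhibitor gene Slpi by 1.67 ± 0.14 (adjusted p = 3.69e-09), Mpeg1 by 1.07 ± 0.15 and the integrin gene Itgb2 by 0.99 ± 0.18. Serpinb2 was higher by 0.68 ± 0.11. Lower were Apol9a (-1.10 ± 0.18), Col4a1 (-0.85 ± 0.16), the interferon-induced gene Gbp2 (-0.80 ± 0.13) and Csf1 (-0.61 ± 0.13). Each group has 3 samples. The calls of 7 of 14 named genes held in all 6 fits without 1 sample; Csf1 lost its call in 4, and Itgb2 and Col4a1 in 1 each. Itgb2 was 0.63 without macrophage replicate 1.

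Of 5 macrophage genes 4 rose, also when adjusted over the list alone, and the list shifted up (camera adjusted p = 1.15e-13). Among these 4, Fcer1g was called in none of the 6 fits without 1 sample. None of 4 fibroblast and matrix genes was called, 2 fell adjusted over the list alone, and the list shifted down (adjusted p = 0.00297, and 0.0498 with an estimated correlation). Of 3 cytokine genes Ccl9 rose and Csf1 fell, the same 2 as adjusted over the list alone (list adjusted p = 0.692). Antigen presentation (adjusted p = 0.187), adipocyte and lipid (0.955), cell cycle (0.759), endothelial (0.234, with Cdh5 lower adjusted over the list alone), lymphocyte (0.692) and immediate early and heat shock (0.176) lists did not shift. Limma called 26 spots, 16 higher and 10 lower, and 17 without stroma-vascular replicate 2. Without stroma-vascular replicate 1, 10 were higher and 12 lower, and array weights gave 192 and 226. Median scaling gave 10 calls, subtraction of each array's 5th percentile 2, and the values without scaling 3, all higher.

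Against the preadipocyte lines, peritoneal macrophages were higher in Ccl9 by 2.45 ± 0.27 (adjusted p = 2.34e-07), Cybb by 2.21 ± 0.26, Serpinb2 by 1.75 ± 0.11 (adjusted p = 2.34e-13), Slpi by 1.41 ± 0.14, the proteoglycan gene Srgn by 1.31 ± 0.18 and Ms4a6d by 1.11 ± 0.19. The galectin gene Lgals1 was lower by -2.57 ± 0.37, Psat1 of serine synthesis by -0.99 ± 0.20 and the chaperonin gene Cct2 by -0.71 ± 0.12. There were 3 samples and 4 lines. Over the 8 fits without 1 sample, 11 of 14 named genes kept their call in each, and Psat1 lost it in 1.

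Of 5 macrophage genes 4 rose, also when adjusted over the list alone, and the list shifted up (adjusted p = 6.65e-15). Of 3 cytokine genes Ccl9 rose (list adjusted p = 0.0966). Antigen presentation (adjusted p = 0.134), fibroblast and matrix (0.0762), cell cycle (0.116) and lymphocyte (0.906) lists had no call over all spots and no shift. Adjusted over each list alone, B2m and Cd79b were higher. Limma called 41 spots, 32 higher and 9 lower, and 21 without macrophage replicate 3. Median scaling gave 16 higher and 2 lower spots, and the values without scaling 8, all higher. Background subtraction gave 15 higher and 12 lower, and array weights 242 and 200.

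Peritoneal macrophages also differed from the macrophage lines Raw 264 and J774, in 167 spots, 94 higher and 73 lower. Slpi was higher by 1.58 ± 0.13 (adjusted p = 3.37e-10), Serpinb2 by 1.52 ± 0.10 (adjusted p = 4.58e-12), Srgn by 1.04 ± 0.17, Selenop by 1.03 ± 0.20, Mpeg1 by 1.03 ± 0.13 and Cd24a by 1.00 ± 0.15. Lower were Lgals1 (-1.88 ± 0.35), the purine synthesis gene Adsl (-1.75 ± 0.41), the cytochrome gene Cyp2e1 (-1.62 ± 0.32), Ilf2 (-1.46 ± 0.29), Rpl27a (-1.37 ± 0.31) and Aldoa (-1.12 ± 0.27). Cyp2e1 is a member of the liver list, yet did not pass in liver against muscle, even adjusted over that list alone. There were 3 samples against 3 and 2. In the 8 fits without 1 sample, 9 of 19 named genes always kept their call; Adsl, Aldoa, Rpl27a and Itgb2 lost it in 3, and Selenop and Ccl9 in 1. Itgb2 was 0.35 and 1.12 without macrophage replicates 1 and 2 in turn.

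Of 5 macrophage genes 3 rose, also when adjusted over the list alone: Mpeg1, Cybb (1.47 ± 0.25) and Itgb2 (0.71 ± 0.17); Fcer1g had -0.07 ± 0.17. The list shifted up (adjusted p = 4.27e-05). Cybb lay at 18.83 on the log2 scale in Raw 264 sample 1, at 16.59 and 16.92 in the other Raw 264 samples, and at 18.28 to 18.84 in the peritoneal macrophages. Ccl9 rose by 1.22 ± 0.26 as 1 of 3 cytokine genes (list adjusted p = 0.118). Antigen presentation (adjusted p = 0.692), cell cycle (0.311), lymphocyte (0.701) and fibroblast and matrix (0.906) lists had no call over all spots and no shift; Cd79b was higher adjusted over its list alone. Without macrophage replicates 2 and 3 in turn the counts were 69 and 66, without J774 replicate 1 it was 53 (24 higher, 29 lower), and median scaling gave 20. Background subtraction gave 26 higher and 32 lower. Without scaling 5 spots were called, all higher.

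Embryonic stem cells without LIF differed from those with LIF in 1 spot, with 3 samples each. Prtg, protogenin, was higher by 0.74 ± 0.12 (adjusted p = 0.00494), and 480 spots had an unadjusted p under 0.05 where 288 would by chance. That excess was not stable: the number was 164 after removal of a local trend. With each sample left out in turn it ranged from 200 to 641. Igf2 had 0.57 ± 0.17 (adjusted p = 0.367), the only 1 of 15 early differentiation genes to pass when adjusted over the list alone; that list did not shift (adjusted p = 0.0589). The pluripotency genes measured, Lefty1 (0.11 ± 0.13) and Klf2 (0.01 ± 0.11), were not called, and cell cycle (adjusted p = 0.595), fibroblast and matrix (0.955) and ribosomal protein (0.176) lists did not shift. No spot was called without replicate 1 of the cells without LIF or replicate 3 of those with LIF, and 4 were called without replicate 3 of the cells without LIF. A fit of these groups alone called 2 higher and 19 lower. Group and array processing cannot be told apart here: median scaling called 1255 spots higher and 467 lower, and the values as deposited 3 higher and 5379 lower, with a median shift of all spots of -1.48.

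The profile of stroma-vascular cells was set against those of macrophages and adipocytes, which tests to which of these the stromal cells lie closer. Across spots, stroma-vascular samples correlated with the peritoneal macrophage mean at 0.163 ± 0.033 (SD, n = 3) and with the adipocyte mean at 0.035 ± 0.127. The difference was 0.127 and positive in 2 of 3 samples (exact permutation p = 0.2, two-sided; the smallest possible is 0.1). Its size depended on the samples and the measure: it was 0.19 without stroma-vascular replicate 1 and 0.072 without replicate 3, and it was 0.023 with Spearman correlation (p = 0.7), 0.019 without centring of spots (p = 0.2) and 0.045 after background subtraction (p = 0.6). The preadipocyte lines correlated with macrophages at -0.098 ± 0.028 (SD, n = 5) and with adipocytes at -0.093 ± 0.119, a difference of -0.005 (exact permutation p = 1). The Hgfu line lay at -0.297 with adipocytes and the other 4 samples between -0.081 and -0.009; the difference was -0.049 without Hgfu. Spots are not independent replicates, and the sign of the preadipocyte difference turned with median scaling, to 0.119. Stroma-vascular samples 1 and 3 correlated best with other groups: 0.178 with embryonic stem cells without LIF and 0.276 with C3H-10T1/2. Stroma-vascular cells and macrophages were both taken 24 h after plating, which was not separated from cell type. The permutation for stroma-vascular cells ignored that only the adipocytes paired with them by replicate number.

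**Figure D2:**
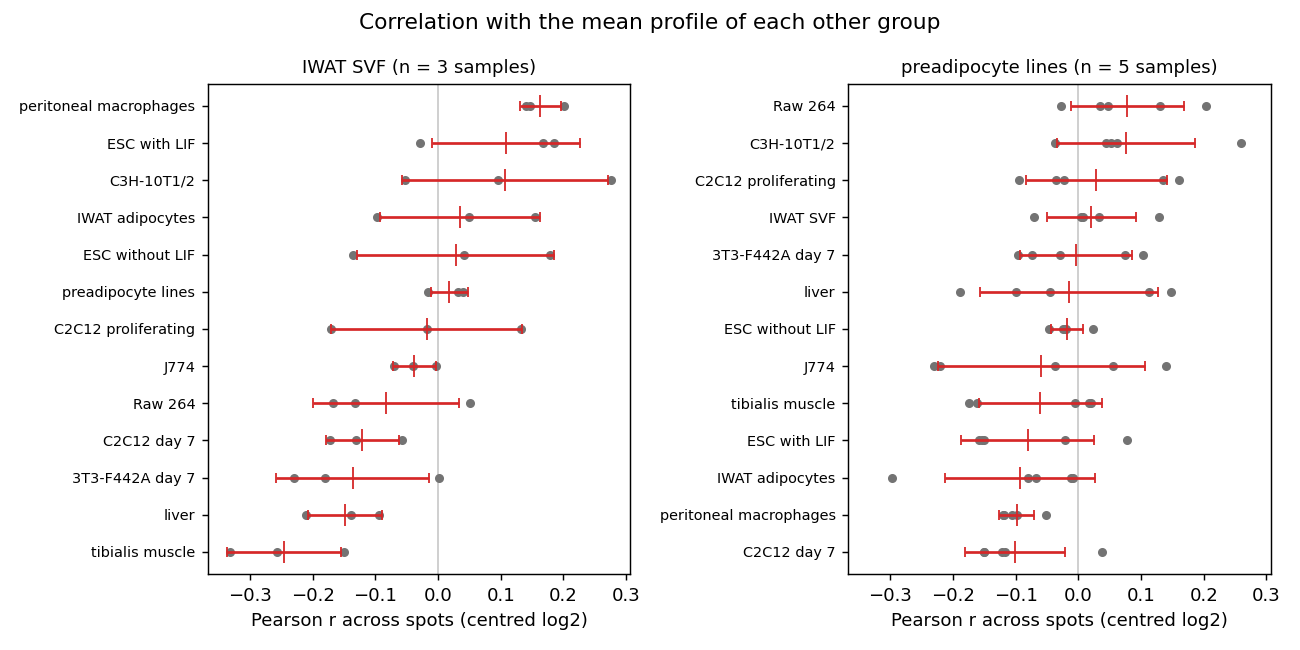
Pearson correlation across spots of each stroma-vascular sample (left) and preadipocyte sample (right) with the mean centred log2 profile of every other group; grey points are samples, red bars mean ± SD. Stroma-vascular samples have their highest mean, 0.163, with peritoneal macrophages, but only sample 2 has its own highest value there (0.201). Sample 1 is highest with embryonic stem cells without LIF (0.178) and sample 3 with C3H-10T1/2 (0.276). The preadipocyte samples lie near -0.098 with macrophages.

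**Figure D3:**
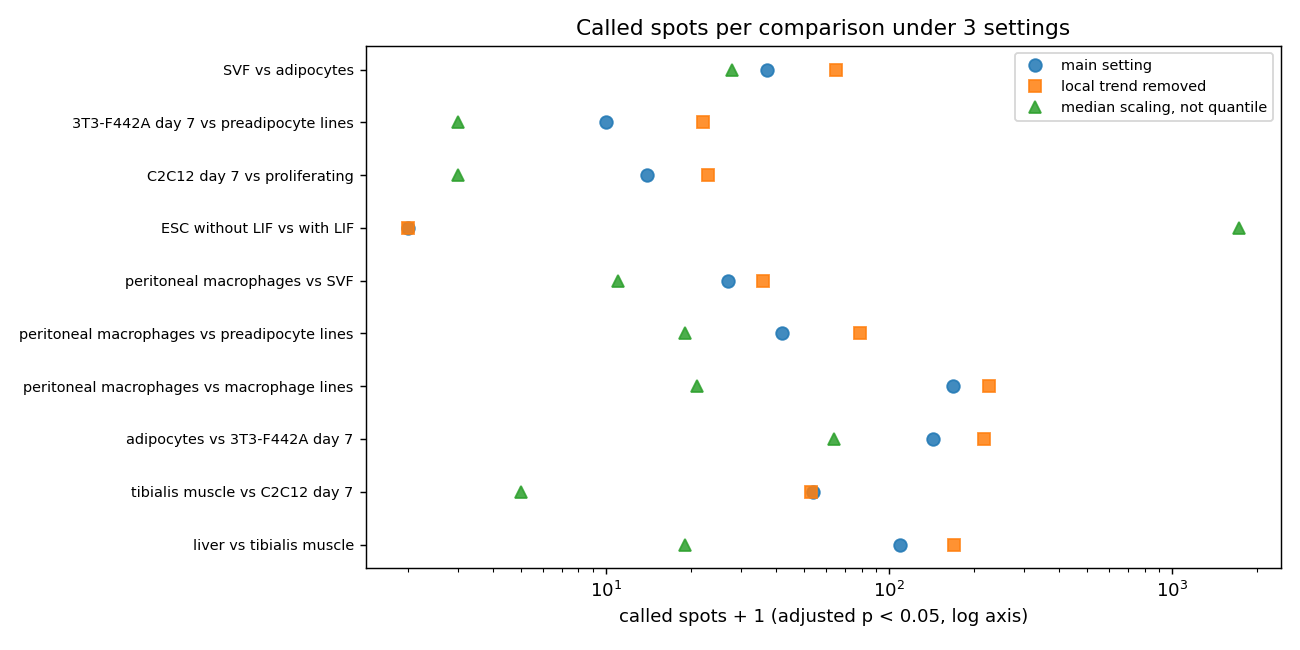
Number of called spots plus 1 per comparison, on a log axis, with quantile normalization (circles), after removal of a local trend over the table of spots (squares) and with median scaling (triangles). The embryonic stem cell comparison goes from 1 to 1722 called spots with median scaling, and the macrophage line comparison from 167 to 20.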

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

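Single samples were tested only among the preadipocyte lines and samples, for the values named next. Among the 4 preadipocyte lines, none of 20 called genes and, among the 5 preadipocyte samples, neither array median nor top brightness had an outlying sample (22 values tested, 0 found). The test was Dixon's ratio, which with 4 or 5 values flags only extreme ones, so an array may stand apart unflagged. The 99th percentile was 3.87 times the median in Hgfu, the lowest of all 40 arrays, and 6.94 to 11.3 times in the other preadipocyte samples. Of 19 genes named for peritoneal macrophages against the macrophage lines, none differed between Raw 264 and J774 after adjustment over these 19. Profile correlations were not tested in this way, and the Hgfu line had the lowest correlation with adipocytes, -0.297. No test was run within the other groups; Cybb in Raw 264 sample 1 lay at 18.83, against 16.59 and 16.92 in the other Raw 264 samples.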

How the results depend on the processing

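Removal of a local trend, background subtraction, array weights, leaving out arrays that stood apart and the crossed numbers were chosen after seeing the data; the other alternatives were not. Values below are counts of called spots where they moved by over 1.5 times; the cause was not tested. Median scaling gave 2 for 3T3-F442A adipocytes, 2 for C2C12, 1722 for embryonic stem cells, 10 for macrophages against stroma-vascular cells, 18 for macrophages against preadipocyte lines, 20 for macrophages against macrophage lines, 63 for adipocytes against 3T3-F442A, 4 for tibialis muscle and 18 for liver. The values without scaling gave 1 for stroma-vascular cells against adipocytes, 0 for 3T3-F442A adipocytes, 0 for C2C12, 5382 for embryonic stem cells, 3 for macrophages against stroma-vascular cells, 8 for macrophages against preadipocyte lines, 5 for macrophages against macrophage lines, 0 for adipocytes against 3T3-F442A, 9 for tibialis muscle and 5632 for liver. An offset 4 times as large gave 8 for C2C12 and 3 for embryonic stem cells. Only spots brighter than the median spot gave 0 for embryonic stem cells, 15 for macrophages against stroma-vascular cells and 70 for liver. Removal of a local trend gave 64 for stroma-vascular cells against adipocytes, 21 for 3T3-F442A adipocytes, 22 for C2C12, 78 for macrophages against preadipocyte lines, 215 for adipocytes against 3T3-F442A and 169 for liver. Subtraction of each array's 5th percentile gave 2 for 3T3-F442A adipocytes, 5 for C2C12, 0 for embryonic stem cells, 2 for macrophages against stroma-vascular cells, 27 for macrophages against preadipocyte lines, 58 for macrophages against macrophage lines and 81 for adipocytes against 3T3-F442A. A fit of only the groups compared gave 112 for stroma-vascular cells against adipocytes, 21 for embryonic stem cells, 289 for adipocytes against 3T3-F442A, 27 for tibialis muscle and 2 for liver. Array weights gave 522 for stroma-vascular cells against adipocytes, 131 for 3T3-F442A adipocytes, 5 for C2C12, 9 for embryonic stem cells, 418 for macrophages against stroma-vascular cells, about 4.4e+02 for macrophages against preadipocyte lines, 1154 for macrophages against macrophage lines, 1504 for adipocytes against 3T3-F442A and 95 for tibialis muscle. The replicate number as a block, in a fit of only the groups compared, gave 231 for stroma-vascular cells against adipocytes, 28 for embryonic stem cells, 15 for macrophages against stroma-vascular cells, 110 for macrophages against macrophage lines, 249 for adipocytes against 3T3-F442A, 184 for tibialis muscle and 6 for liver. A trended and robust variance gave 6 for C2C12. The single 3T3-F442A preadipocyte sample as baseline, whose spread is taken from the other groups, gave 35 for 3T3-F442A adipocytes. Leaving out C3H-10T1/2 sample 3 and the third array with LIF, which resemble each other, gave 0 for embryonic stem cells. Crossed numbers for liver and muscle, whose deviations correlated at -0.111, gave 4 for liver.

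Without scaling, 26 named values changed sign, beside median shifts of all spots of -1.48 in embryonic stem cells, 1.08 in tibialis muscle and -1.53 in liver. For embryonic stem cells these were Prtg -0.67, Lefty1 -1.35, Klf2 -1.46, Igf2 -0.87, Hoxa5 -1.12, Col4a1 -1.28, Sox17 -1.24, Serpinh1 -1.12, Ezh2 -1.30 and Mki67 -1.31. For tibialis muscle these were Stac3 0.42, H19 0.12, Clip3 0.35, Tceal9 0.43, Rassf6 0.44 and Bmp1 0.42. For liver these were Mgst1 -0.016, Selenop -0.082, Scp2 -0.43, Cyb5a -0.28, Pzp -0.31, Enpp5 -0.58, Hpx -0.43, Fgb -0.66, Ndufaf7 -1.04 and Hbb-b1 -1.04. In the other comparisons that median shift was -0.27 for stroma-vascular cells against adipocytes, 0.40 for 3T3-F442A adipocytes, -0.13 for C2C12, 0.28 for macrophages against stroma-vascular cells, 0.44 for macrophages against preadipocyte lines, 0.20 for macrophages against macrophage lines and 0.06 for adipocytes against 3T3-F442A.

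Leaving out each replicate in turn gave counts from 14 to 37 for stroma-vascular cells against adipocytes, 6 to 32 for 3T3-F442A adipocytes, 3 to 153 for C2C12, 0 to 4 for embryonic stem cells, 17 to 22 for macrophages against stroma-vascular cells, 21 to 49 for macrophages against preadipocyte lines, 53 to 185 for macrophages against macrophage lines, 34 to 275 for adipocytes against 3T3-F442A, 11 to 163 for tibialis muscle, 48 to 199 for liver. A group left with 1 sample is assumed to vary like the other groups. With a replicate left out, the profile difference ranged from 0.072 to 0.19 for stroma-vascular cells and from -0.049 to 0.043 for the preadipocyte lines, and was 0.119 for the latter with median scaling. For stroma-vascular cells it went from 0.127 to 0.023 (p = 0.7) with Spearman correlation, 0.019 (p = 0.2) without centring and 0.045 (p = 0.6) after background subtraction.

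Of the groups with 3 pairs, same-numbered samples correlated above 0.1 in every pair only for stroma-vascular cells and adipocytes, where all 6 samples correlated best with their own number. With 2 pairs, which do not settle it, the correlations were 0.139 and 0.15 for macrophages and J774. They were 0.06 and 0.109 for C2C12, and 0.101 for tibialis muscle and C2C12. Each sample with a same-numbered partner correlated best with it. In a group of 2 samples the deviations are mirror images, so these agreements are not separate evidence. A floor in place of the offset and leaving out the 3 differently processed arrays kept every count they apply to within 1.5 times. A block for the membrane was not run. Intensities close to background limit what small changes can be seen.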

Other observations

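The comparisons in the next paragraph were not in the design fixed at the start. The tests of neighbouring spots, of the processing of the 3 arrays without LIF and of the first principal component were chosen only after the results they address were seen; the splits of samples and the spread of the embryonic stem cell groups were not, though the rule for reading that spread was changed after its value was seen.

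Stroma-vascular cells exceeded the preadipocyte lines in 10 spots and were lower in 1. B2m, the light chain of MHC class I, was higher by 1.84 ± 0.40, Gbp2 by 0.99 ± 0.13, Apol9a by 0.98 ± 0.17, Serpinb2 by 1.07 ± 0.11 and Glul, glutamine synthetase, by 0.65 ± 0.14. C3H-10T1/2 cells differed from the preadipocyte lines in 1 spot without a gene, with 502 spots at an unadjusted p under 0.05. Raw 264 was lower than J774 in 6 spots, among them Pacc1 (-1.71 ± 0.30), Trappc13 (-1.03 ± 0.21) and Mocs2 (-0.81 ± 0.15).

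Called spots lay next to each other in the table more often than by chance: 104 of 596 calls, summed over the 10 comparisons, had a called spot of the same direction 1, 12 or 24 places away, against a median of 35 and a highest value of 61 in 1000 random placements. This is what background or spill-over shared by neighbouring spots may give. Fgfr4 (0.68 ± 0.15) and Pex7 (0.61 ± 0.14), on either side of Tmsb10 (2.66 ± 0.50) and called with it in stroma-vascular cells, are examples picked after their values were seen. As the whole cause of the calls, regional background is argued against by the 537 calls that held in the same direction after a local trend along the table was removed, as far as the table's order follows the layout of the membrane, which is not given in the sources used here. Clones placed by gene function, a biological alternative, were not tested.

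The single call between embryonic stem cells without and with LIF has open explanations. The median spot's SD within these groups was 0.137, against a median of 0.139 in the other 9 comparisons. This SD says little about the number of calls, because all 14 groups share a residual spread: the median SE was 0.134 here and also in the comparisons with 26, 36 and 142 calls. The 3 arrays without LIF have a 99th percentile at least 60.0 times the median and were all processed unlike the others, so processing and a biological effect of LIF cannot be told apart.

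The first principal component, 18.8% of the variance, had a mean score higher by 9.52 in the 13 tissue and primary samples than in the 27 cultured ones. Only 5 of the 13 lay above every cultured sample. The highest cultured score, 9.58, was that of replicate 2 without LIF, one of the 3 differently processed arrays. Apart from those 3 arrays the highest was 5.26, in C2C12 day 7 replicate 1. Within groups the component's rank correlation with the brightness of an array's top spots over its median was 0.29 (permutation p = 0.116). Pearson r was 0.301 (permutation p = 0.0557), and 0.347 without the 2 samples farthest out, which leaves brightness open as a possible explanation. A trend along the table of spots is argued against, since the gap was 95.8% of its size after its removal; how far this holds for position on the membrane is open, as the layout is not given in the sources used here. Tissue of origin, the biological alternative, was not tested apart from these.

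Other splits of the same samples were fitted in the same way. For peritoneal macrophages, only the real split gave as many calls. It was 1 of 35 against the preadipocyte lines (41 calls, highest other 25) and 1 of 56 against the macrophage lines (167 calls, highest other 112). Both shares are under 0.05 and the smallest these splits allow, without adjustment for the number of comparisons split. Where samples may be technical, such splits do not exclude chance between cultures or animals. For 3T3-F442A adipocytes, 2 of 35 splits gave at least the 9 calls, the highest other 12, so chance is not excluded for that count. With 10 splits no share under 0.05 is possible: the real and highest other counts were 36 and 2 for stroma-vascular cells against adipocytes, 26 and 1 for macrophages against stroma-vascular cells, 142 and 0 for adipocytes against 3T3-F442A cells, and 1 and 1 for embryonic stem cells. Among the 4 splits that part all 3 pairs of stroma-vascular cells and adipocytes, the blocked fit called 231 spots in the real one and 0 in each other. These splits cannot decide on chance, since 4 allow no share under 0.05. Each other split also exchanges the groups in 1 of the 3 pairs. The difference between groups then adds to the residual spread, so few calls could arise there.

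Only 21 of the 40 arrays had their highest correlation with an array of their own group, and 24 after removal of the local trend.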
